A study of Homo sapiens with 60 samples.

How the data were processed

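RNA from U-2 OS Tet-off lines stably expressing the glucocorticoid receptor form alpha, A, B, C or D was measured at 0, 6, 12 and 24 h of 100 nM dexamethasone, with 3 arrays for each of the 20 combinations of line and time, 60 in all. Per the labels, 500 ng of total RNA was labelled with Cy3 only, 1.5 ug of cRNA was hybridized for 17 h to Agilent human 44K arrays, and slides were scanned on an Agilent G2565 scanner at 10 micron with extended dynamic range. Groups were taken from the sample titles. In 1 sample, B 0 h replicate 1, the source name gave alpha where the title gave B. Its profile correlated 0.42 with the other B arrays and -0.27 with alpha over the 2000 most variable genes, so the title was used. Across all samples 59 of 60 arrays were nearest to their own line by this measure. The exception, C 24 h replicate 3, is one of the doubtful arrays named below: it correlated 0.18 with alpha and 0.06 with C, and was kept in its labelled group. The labels do not say whether replicates were separate cultures.

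The intensity values of each array were made by the authors with Agilent Feature Extraction 9.1, which per the file headers detrended the signal within the array, put surrogate values in place of dim spots and did no scaling between arrays. The mean spot signal and local background median of the same files are intensities that, per the file headers, had no such treatment. The log2 values of the series matrix were deposited after Rosetta Resolver 6.0, which per the labels did pre-processing and error modelling. Their normalization between arrays was not stated: each column had a median between 5.87 and 6.15 and correlated 0.984 to 0.999 (median 0.998) with the log2 scanner signal of its array. The series matrix held 951 missing values. It was used as an alternative only.

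All further steps were computed from the scanner files with R 4.3.3, limma 3.58.1 and data.table (1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Each array had 43931 spots, 41675 of them not controls. Spots marked by Feature Extraction as non-uniformity or population outliers were set missing (0 to 261 per array, median 8), replicate spots of a probe were averaged, and log2 signals were scaled by subtracting the 75th percentile of the array. Of 41000 probes, 29039 (70.8%) were well above background on all 3 arrays of at least 1 group and were kept. Probes were matched to gene symbols by accession (23146), symbol (2436) or older symbol (1114), and 14304 stayed unmatched and kept the name given in the files. Where a gene had more than 1 kept probe (5530 genes), the probe with the highest mean stood for it. This left 21822 genes, 14194 with a reference gene and 7628 without. Of these, 461 had a missing value on some array.

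Depth was judged by signal over background. The 75th percentile of log2 signal ran from 5.57 to 9.02 between arrays, its distance to the median from 1.41 to 3.09 (median 2.75), and the slope of the spike-in controls from 0.900 to 1.02 (median 0.966). The 5 arrays with a 75th percentile under 7 or within 2 of the median (alpha 24 h replicates 2 and 3, C 12 h replicate 3, C 24 h replicate 3 and D 6 h replicate 3) are called the doubtful arrays. They were kept and left out as an alternative. Leaving them out leaves a single array of alpha at 24 h, so values for that group without them rest on a single array. Where no array of a group was well above background, the fold is a lower limit: the mean of the other group against the background limit of the dim group.

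The tests, comparisons, alternatives and rules for naming genes were fixed before the data were examined, except where said. The limma model gave each of the 20 groups a mean in 1 fit (40 residual and 2.62 prior degrees of freedom, no covariates), with moderated 2-sided tests and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05 and at least 1.5-fold. There were 15 dexamethasone responses (6, 12 and 24 h against 0 h in each line), 10 differences between pairs of lines in the mean response over the 3 times, 4 untreated lines against alpha and 5 comparisons of 24 h with 6 h, and an F test over all line-by-time terms, run on the 21361 genes with no missing value. Named genes were NR3C1, the 10 highest and 8 lowest in the common response, the 3 largest in each direction per response at 6 and 24 h (all treated arrays beyond all untreated ones), per pair and per late comparison, and the 4 largest per untreated comparison. From gene lists, the called members with the largest changes came first.

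The 17 gene lists were classical glucocorticoid-induced genes, inflammatory and matrix-protease genes that glucocorticoids are known to repress, S-phase and mitosis genes, G1 regulators and cyclin-dependent kinase inhibitors, metallothioneins, cholesterol synthesis and uptake genes, pro-apoptotic and anti-apoptotic genes, p53 target genes, osteoblast and bone genes, extracellular matrix and adhesion genes, circadian clock genes, unfolded protein and integrated stress response genes, interferon-stimulated genes, the glucocorticoid receptor with its chaperones and cofactors, and epithelial and haematopoietic markers of other cell types. Lists were tested with camera in limma at its preset inter-gene correlation of 0.01 and again with the correlation estimated, adjusted over lists and comparisons of a family, and members were counted both at the genome-wide adjustment and adjusted over the list alone. In all, 14 genes were in 2 lists. Overlaps between lines were compared with the product of the 2 shares. Times of 1 line share their untreated arrays, so their correlation (0.662 to 0.911) was set beside that of simulated unrelated responses with the same arrays shared (0.480 to 0.516), and is not reported as a result.

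The code was tested on simulated data drawn from the mean and residual spread of each gene, with 200 genes changed. Dexamethasone responses of log2 1, 2, 3 and 4 were recovered for 50, 80, 82 and 100% of genes with 12 unchanged genes called, differences between lines for 24, 64, 94 and 98% with 8, and untreated differences for 56, 74, 94 and 98% with 11. A moved list of 20 genes had a camera p of 4.35e-35, and 5 of 100 unmoved lists passed. Genes were drawn independently and without slide sets or a background floor, so this does not test the preset correlation on lists whose genes move together.

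Alternatives were normexp background correction (offset 50) of the mean spot signals, quantile normalization, scaling by the array median, no filter on dim probes, a filter for probes well above background on all 60 arrays, the mean of a gene's probes, a fit of only the groups compared, the values processed by the authors, arrayWeights, and leaving out each array in turn. Blocks in the fit were the replicate number, the line-by-replicate combination, the scanner (2) and the slide set (13), the last also as a random effect where it could not be a fixed one. Scan days were not used as a block because 59 arrays fell on the first and 1 on the later. Leaving out the doubtful arrays was added after the array signals were seen. The closing section gives the effects.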

Results

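The series held 60 one-colour Agilent arrays of U-2 OS osteosarcoma cells, a human bone tumour line, in which a coding sequence of the glucocorticoid receptor had been placed under a tetracycline-repressible promoter. The lines were named alpha, A, B, C and D for the receptor form each stably expressed, and each line was sampled untreated (0 h) and after 6, 12 and 24 h of 100 nM dexamethasone, a synthetic glucocorticoid. Every one of the 20 combinations of line and time had 3 arrays. The 75th percentile of the log2 signal ranged from 5.57 to 9.02 between arrays (median 8.50), and 45.5 to 85.9% of non-control spots lay well above background (median 66.0%). At most 6 spots of an array were saturated. After filtering, 21822 genes were tested. Changes are given as log2 values ± standard error (SE) with limma p-values adjusted for all genes, n = 3 arrays in each group, and a gene was called when its adjusted p was under 0.05 and its change reached 1.5-fold. These p-values use each gene's within-group spread pooled over all 20 groups. Samples of a group may be technical replicates, as the labels do not say. Each receptor form was present in a single line, so an effect of the form and an effect of the clone could not be told apart. No line was sampled at 6, 12 or 24 h without dexamethasone, and arrays of different times lay on different slide sets. Effects of dexamethasone, of time in culture and of the slide set could therefore not be told apart. Changes from 0 h are called dexamethasone responses for short.

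The first question was whether the receptor gene itself differed between lines or moved with the hormone. NR3C1, which encodes the glucocorticoid receptor, was not called different between the untreated lines. Against alpha the difference was -0.16 ± 0.23 in A (adjusted p = 0.840), -0.52 ± 0.23 in B (adjusted p = 0.150), -0.51 ± 0.23 in C (adjusted p = 0.164) and -0.13 ± 0.23 in D (adjusted p = 0.831). After 6 h of dexamethasone NR3C1 fell in alpha (-1.39 ± 0.23, 2.62-fold, adjusted p = 5.56e-06), A (-1.31 ± 0.23, adjusted p = 1.61e-05) and C (-1.19 ± 0.23, adjusted p = 7.25e-05). It was unchanged by the test in B (-0.37 ± 0.23, adjusted p = 0.398) and D (-0.66 ± 0.23, adjusted p = 0.0550). By 24 h NR3C1 remained lower in alpha (-1.09 ± 0.23, adjusted p = 9.08e-05), A (-0.75 ± 0.23, adjusted p = 0.00622) and C (-0.78 ± 0.23, adjusted p = 0.00405). In B NR3C1 was higher at 24 h than at 6 h (0.65 ± 0.23, adjusted p = 0.0360). Averaged over the times, the NR3C1 response was higher in B than in alpha by 1.18 ± 0.26 (adjusted p = 0.00216) and higher in D than in alpha by 0.79 ± 0.26 (adjusted p = 0.0360). The D call was lost under 6 alternative settings, the late rise in B under 5, and the B difference and the 24 h fall in A under median scaling alone. The 24 h fall in C was lost without the doubtful arrays and in a fit of only the groups compared. A second NR3C1 probe gave 6 h changes of -1.49 in alpha, -1.62 in A, -0.60 in B, -1.78 in C and -0.58 in D. Whether either probe reads the introduced coding sequence, the cell's own receptor transcript or both could not be settled from the files.

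**Figure D1:**
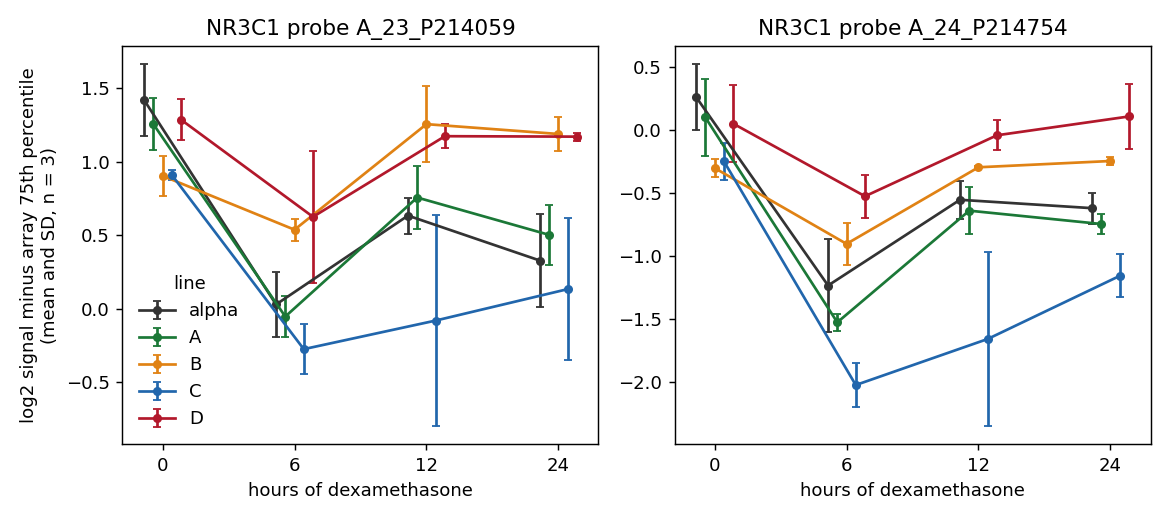
Signal of the 2 NR3C1 probes (log2, relative to the 75th percentile of the array, mean and SD of 3 arrays) against hours of dexamethasone for the lines alpha, A, B, C and D. For the tested probe (left) the alpha mean went from 1.42 at 0 h to 0.03 at 6 h and the B mean from 0.91 to 0.54.

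The next question was which genes changed after dexamethasone in every line. Called higher in all lines were 592 genes at 6 h and 875 at 24 h, and called lower in all lines were 319 and 795. The largest common rise was read by probes for FAM90A2P, FAM90A1 and FAM90A10, a primate gene family of near-identical copies that these probes cannot separate, so which copy rose is uncertain. FAM90A2P rose by 9.55 ± 0.31 in alpha (751-fold, adjusted p = 5.93e-27) and by 8.44 ± 0.31 in D (347-fold, adjusted p = 9.10e-25) at 6 h, and by 13.72 ± 0.31 in C at 24 h (adjusted p = 1.86e-33). ACTL8, an actin-like gene normally restricted to testis, rose at 24 h by 11.55 ± 0.42 in alpha (at least 1206-fold, adjusted p = 6.56e-25) and by 6.89 ± 0.42 in D (at least 33.8-fold, adjusted p = 7.90e-17). Where no array of a group read a gene above background, the fold is given as at least the ratio to the background limit. S100P, a calcium-binding protein of placenta and many carcinomas, rose at 24 h in alpha by 8.60 ± 0.35 (at least 237-fold, adjusted p = 3.66e-23) and in B by 9.68 ± 0.35 (at least 355-fold, adjusted p = 4.97e-25). TF, the iron carrier transferrin, had already risen at 6 h by 6.15 ± 0.38 in alpha (at least 50.5-fold, adjusted p = 3.56e-17) and 5.79 ± 0.38 in D (at least 38.9-fold, adjusted p = 7.73e-16). SPINK13, a serine protease inhibitor, rose by 7.38 ± 0.58 in D at 6 h (at least 45.9-fold, adjusted p = 3.09e-13), and the stomach proton pump ATP4A by 9.21 ± 0.44 in C (at least 128-fold, adjusted p = 6.29e-21). The pancreatic lipase PNLIP rose at 24 h by 6.07 ± 0.83 in alpha (adjusted p = 6.79e-08) and by 9.98 ± 0.83 in B (at least 203-fold, adjusted p = 5.67e-13).

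Among the genes that fell in every line, PTPRR, a phosphatase that restrains MAP kinases, fell at 24 h by 4.68 ± 0.72 in alpha (at least 9.42-fold, adjusted p = 7.70e-07) and by 4.56 ± 0.72 in D (adjusted p = 5.66e-06). AMIGO2, a neuronal adhesion and survival gene, fell at 6 h in alpha (-4.77 ± 0.45, 27.3-fold, adjusted p = 1.57e-11) and D (-4.63 ± 0.45, 24.8-fold, adjusted p = 1.01e-10). LFNG, which sugar-modifies Notch receptors, fell at 24 h by 3.03 ± 0.68 in alpha (adjusted p = 0.000266) and by 5.17 ± 0.68 in D (at least 21.3-fold, adjusted p = 1.39e-07). FHL2, a transcriptional cofactor of bone and muscle, fell at 6 h by 3.70 ± 0.33 in alpha (adjusted p = 2.52e-12) and 3.29 ± 0.33 in D (adjusted p = 2.10e-10). The matrix protease ADAMTS6 fell more in alpha (5.34 ± 0.43 at 6 h, adjusted p = 2.79e-13) than in D (2.62 ± 0.43, adjusted p = 2.30e-05). CCL2, a monocyte chemokine that glucocorticoids repress, fell at 6 h in all lines, from -2.80 ± 0.59 in alpha (at least 4.56-fold, adjusted p = 0.000327) to -4.75 ± 0.59 in A (26.9-fold, adjusted p = 2.11e-08). At 24 h it was still lower in D (-4.38 ± 0.59, adjusted p = 2.14e-07) but unchanged in alpha (-1.27 ± 0.59, adjusted p = 0.0659). F2RL2, a thrombin receptor, fell in alpha by 5.75 ± 0.74 at 24 h (adjusted p = 1.57e-08). In 1 of 15 comparisons a second probe of the same gene went the other way, with both changes at least 1.5-fold.

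**Figure D2:**
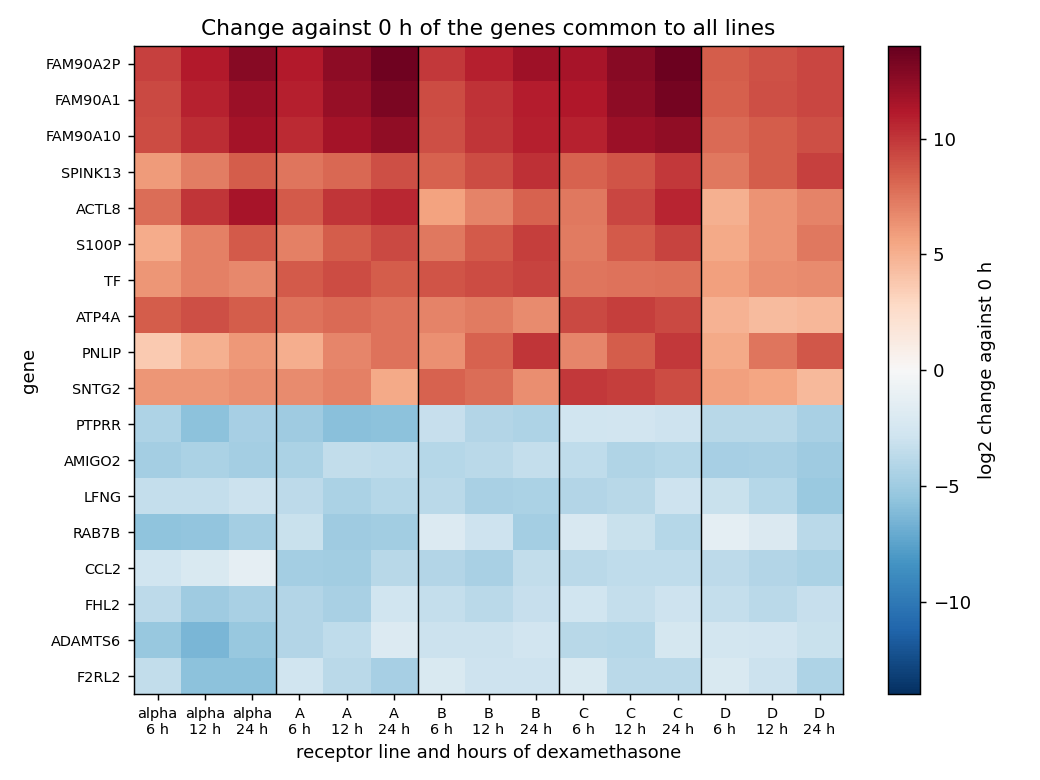
Change against 0 h (colour, log2) of the 18 genes with the largest common responses (vertical) in each line after 6, 12 and 24 h (horizontal). FAM90A2P reached 13.72 in C at 24 h and ADAMTS6 reached -6.38 in alpha at 12 h.

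How many genes moved in each line and when was asked by counting calls among the 21822 genes. At 6 h, 2238 genes rose and 1677 fell in alpha, 2410 and 1639 in A, 1591 and 914 in B, 2795 and 2047 in C, and 1212 and 727 in D. At 12 h the numbers were 3506 and 2863 in alpha, 4150 and 3031 in A, 2588 and 2233 in B, 5553 and 3905 in C, and 1313 and 906 in D. At 24 h they were 6127 and 4662 in alpha, 4083 and 4148 in A, 2500 and 2679 in B, 5867 and 4236 in C, and 1518 and 1482 in D. Called changes of 4-fold or more numbered 2111 higher and 841 lower in alpha at 24 h, 2358 and 338 in C, and 419 and 316 in D. Some tested genes were dim on every untreated array of a line and kept for being brighter elsewhere. At 24 h 1032 of 1420 such genes were called higher in alpha, 1080 of 1529 in C and 205 of 1184 in D. Over all genes dim in the other untreated lines the median change was 1.74 in alpha, 1.47 in C and 0.142 in D. Without the doubtful arrays it was 0.0785 in alpha (a single array), 0.366 in C and 0.142 in D. Their share in the excess over D was not settled. Over all alternatives the numbers called at 6 h ran from 2440 to 6806 in alpha, 2443 to 5430 in A, 1453 to 4161 in B, 2841 to 6011 in C and 262 to 3321 in D, the last lowest in a fit of only the groups compared and 1167 to 3258 with 1 array left out. On the arrays of the first scanner alone, which held 11 of the 15 responses, 99.8 to 100% of the called genes had the same direction, and on the second, with all 15, 99.65 to 100%. They were called on these arrays too, so this did not test a scanner effect. The share that rose depended on the scaling of the arrays, which moved the median change of all genes by -0.70 to -0.04 with median scaling, by -0.28 to 0.003 with quantile normalization and by -0.31 to 0.009 in the values processed by the authors. With quantile normalization, 4380 genes rose and 5436 fell in alpha at 24 h, 3901 and 4710 in C at 12 h, 4128 and 5390 in C at 24 h, and 799 and 966 in D at 6 h. In the values processed by the authors the pairs were 4203 and 5627 in alpha at 24 h, 4067 and 4630 in C at 12 h, 4103 and 5285 in C at 24 h, and 683 and 974 in D at 6 h. Median scaling gave 1952 and 3181 in alpha at 12 h, 3098 and 6773 in alpha at 24 h, and 1402 and 1652 in A at 6 h. It also gave 2267 and 3790 in A at 12 h, 2892 and 6712 in C at 12 h, 2864 and 7833 in C at 24 h, 548 and 1024 in D at 6 h, and 621 and 692 in D at 12 h. Background correction by normexp gave 8696 and 3823 in alpha at 24 h and 2444 and 877 in D at 6 h.

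**Figure D3:**
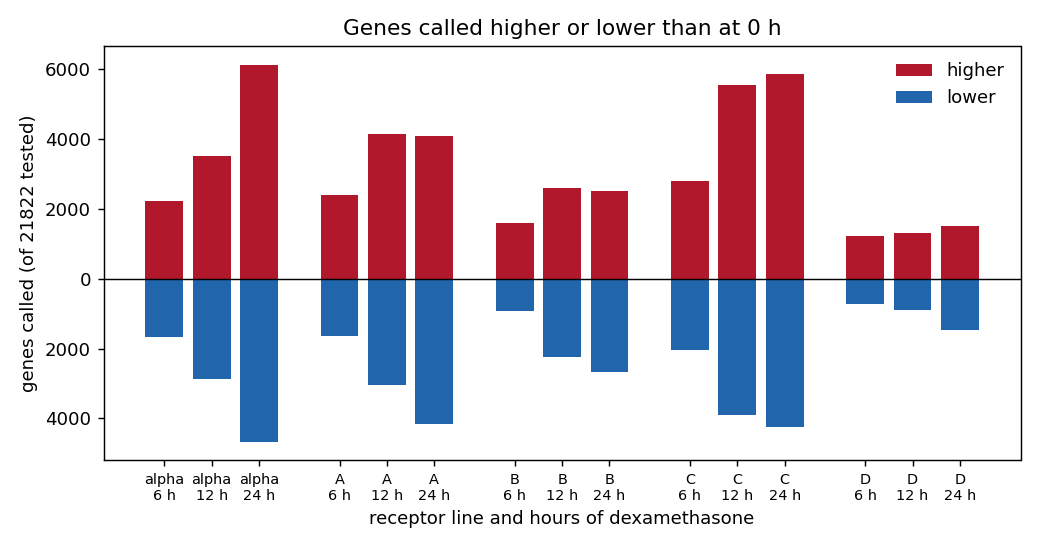
Number of genes called higher (up) or lower (down) than at 0 h for each line after 6, 12 and 24 h of dexamethasone, of 21822 tested. At 24 h the alpha line had 6127 higher and 4662 lower and the D line 1518 higher and 1482 lower.

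Some of the genes with the deepest falls at 24 h fell in the other lines too. TGFBI, an extracellular matrix protein induced by TGF-beta, fell by 5.79 ± 0.67 in alpha (adjusted p = 1.61e-09), 5.18 ± 0.67 in B (adjusted p = 6.42e-08), 4.14 ± 0.67 in C (adjusted p = 2.25e-06) and 5.42 ± 0.67 in D (42.8-fold, adjusted p = 3.87e-08). The keratin KRT80 fell by 6.02 ± 0.39 in alpha (64.8-fold, adjusted p = 7.03e-17) and by 3.47 to 4.11 in the other lines, and in alpha the annexin ANXA10 fell by 5.83 ± 0.59 (adjusted p = 3.89e-11). CSRP3, a muscle LIM protein, fell by 5.68 ± 1.03 in A (at least 20.7-fold, adjusted p = 1.73e-05) and 4.59 ± 1.03 in B (adjusted p = 0.000617), and MAP1LC3C, an autophagy gene, fell by 5.43 ± 1.16 in A (at least 9.04-fold, adjusted p = 0.000190). In D the hair keratin KRT75 fell by 6.34 ± 0.79 (at least 34.1-fold, adjusted p = 4.63e-08) and the water channel AQP1 by 5.43 ± 0.39 (43.2-fold, adjusted p = 1.16e-14). AQP1 changed by -5.42 in A, -4.47 in B, -3.52 in alpha and -3.33 in C.

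Whether genes known from other tissues to be induced by glucocorticoids rose here was asked of 33 measured genes of a list of 35. Of these, 17 rose, 3 fell and 13 did neither in alpha at 24 h (18 and 3 adjusted over the list alone). The camera adjusted p was 0.0126 at the preset correlation of genes in a list, and 0.854 with the correlation estimated from the data, given below as the estimated-correlation p, also adjusted. In A, 23 rose and 1 fell (26 and 1 over the list alone, camera adjusted p = 1.53e-07, estimated-correlation p = 0.684), and in C 21 rose and 1 fell (22 and 1, camera adjusted p = 2.21e-05, estimated-correlation p = 0.741). B had 20 higher and 2 lower (25 and 2, camera adjusted p = 4.12e-11, estimated-correlation p = 0.684) and D had 13 higher and 1 lower (16 and 1, camera adjusted p = 2.37e-07, estimated-correlation p = 0.684). RGS2, which dampens G-protein signals, rose at 24 h by 5.77 ± 0.25 in alpha (adjusted p = 1.25e-22), 6.96 ± 0.25 in C (adjusted p = 1.53e-25) and 3.65 ± 0.25 in D (adjusted p = 1.87e-15). PDK4, which slows glucose oxidation, rose by 5.13 ± 0.81 in alpha (adjusted p = 1.08e-06) and 7.14 ± 0.81 in C (adjusted p = 9.56e-10). SGK1, a kinase of sodium transport, rose by 4.29 ± 0.32 in alpha (adjusted p = 7.26e-15) and 5.74 ± 0.32 in C (adjusted p = 6.76e-19), and TSC22D3, the glucocorticoid-induced leucine zipper, by 3.16 ± 0.64 in D (adjusted p = 0.000307). HSD11B2, which inactivates cortisol, rose at 6 h by 4.22 ± 0.39 in alpha, 5.83 ± 0.39 in C and 2.47 ± 0.39 in D.

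Inflammatory and matrix-protease genes known to be repressed by glucocorticoids were lower early. Of 22 measured members, 1 rose and 8 fell in alpha at 6 h (2 and 8 over the list alone, camera adjusted p = 0.00796, estimated-correlation p = 0.741), and 1 rose and 11 fell in A (1 and 11, camera adjusted p = 0.000578, estimated-correlation p = 0.684). LIF, a cytokine of the interleukin-6 family, fell at 6 h by 2.81 ± 0.25 in alpha (adjusted p = 4.17e-12), 3.58 ± 0.25 in A (adjusted p = 2.33e-15) and 1.79 ± 0.25 in D (adjusted p = 9.21e-07). CXCL8, a neutrophil chemokine, fell by 3.66 ± 0.91 in alpha (adjusted p = 0.00229). The urokinase gene PLAU fell at 24 h in B (-4.29 ± 0.52) and D (-4.18 ± 0.52). Some members moved the other way. NOS2, the inducible nitric oxide synthase, rose at 6 h by 3.46 ± 0.23 in alpha (adjusted p = 3.90e-16), TNF rose by 4.98 ± 0.66 in alpha at 24 h (at least 14.7-fold, adjusted p = 3.66e-08), and the chemokine CXCL1 rose by 5.60 ± 0.75 in C at 24 h (at least 10.2-fold, adjusted p = 4.50e-08). By 24 h, 10 members were higher and 4 lower in alpha (camera adjusted p = 0.446, estimated-correlation p = 0.894). Without the doubtful arrays, which leaves a single alpha array, fewer rises were called and the median change was 0.58. In D 1 was higher and 6 lower (1 and 8 over the list alone, camera adjusted p = 0.00239, estimated-correlation p = 0.684).

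Genes of S phase and mitosis were lower at 24 h. At 24 h, of 40 measured members, 33 fell and none rose in alpha (34 over the list alone, camera adjusted p = 9.67e-11, estimated-correlation p = 0.684). In A 35 fell (36, camera adjusted p = 4.99e-12, estimated-correlation p = 0.684) and 37 fell in C (37, camera adjusted p = 4.08e-14, estimated-correlation p = 0.684). B had 15 lower (16, camera adjusted p = 2.27e-05, estimated-correlation p = 0.773) and D had 4 lower (4, camera adjusted p = 0.00545, estimated-correlation p = 0.854). CCNB1, the cyclin that drives mitosis, fell by 3.50 ± 0.67 in alpha (adjusted p = 2.85e-05), and the centromere histone CENPA by 2.69 ± 0.45 in alpha (adjusted p = 2.89e-06). The kinase AURKB fell by 2.12 ± 0.39 in A (adjusted p = 2.67e-05) and the spindle checkpoint kinase TTK by 2.11 ± 0.25 in C (adjusted p = 3.95e-09). In D the members that fell included TYMS, which makes thymidylate (-0.92 ± 0.15, adjusted p = 1.31e-05), and PCNA, the sliding clamp of replication (-0.85 ± 0.18, adjusted p = 0.000438). The mean level of the group went from 2.93 to 1.60 in alpha between 0 and 24 h, from 2.62 to 1.20 in C and from 2.60 to 2.30 in D, where the list did not pass at 6 h (camera adjusted p = 0.357) or 12 h (camera adjusted p = 0.354). Regulators of G1 were lower in alpha at 6 h, when the S-phase and mitosis list also passed in A (camera adjusted p = 0.0204, estimated-correlation p = 0.859, and 0.0974 with quantile normalization) and C (camera adjusted p = 0.00198, estimated-correlation p = 0.841). Of 17 G1 genes measured, 7 fell and none rose in alpha at 6 h (8 over the list alone, camera adjusted p = 0.000366, estimated-correlation p = 0.684). In D the G1 list call at 6 h (camera adjusted p = 0.0129) was lost with quantile normalization (adjusted p = 0.215). The growth regulator MYC was lower by 2.44 ± 0.28 in alpha and 2.01 ± 0.28 in D and the kinase CDK6 by 1.98 ± 0.22 in alpha and 1.97 ± 0.22 in D. CDK4 fell by 2.61 ± 0.20 in alpha at 24 h, whereas the stress gene GADD45B rose by 2.33 ± 0.38 in alpha and 3.55 ± 0.38 in C.

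**Figure D4:**
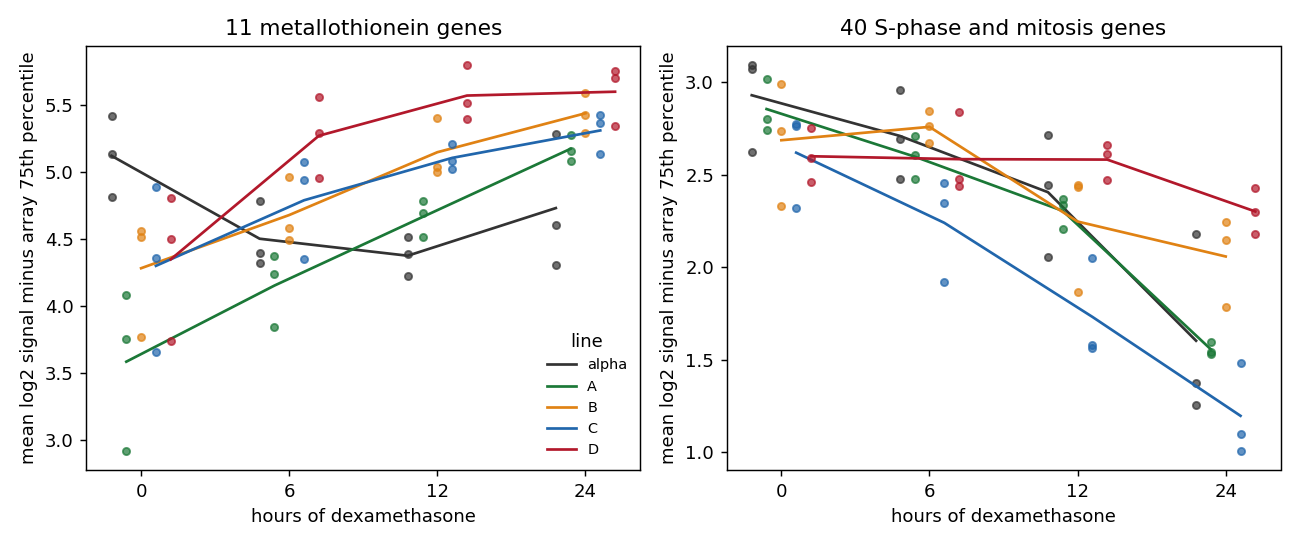
Mean level (log2 relative to the 75th percentile of the array) of 11 metallothionein genes (left) and 40 S-phase and mitosis genes (right) in each array (points) and line (lines) against hours of dexamethasone. The metallothionein mean was 5.12 at 0 h and 4.38 at 12 h in alpha, and 3.58 at 0 h and 5.17 at 24 h in A.

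Metallothioneins, which bind zinc and copper and are known to be induced by glucocorticoids, rose at 24 h in A, B and D. At 24 h, 9 of 11 measured members rose in A (9 over the list alone, camera adjusted p = 0.000423, estimated-correlation p = 0.684), 8 in B (9, camera adjusted p = 0.00121, estimated-correlation p = 0.684) and 8 in D (9, camera adjusted p = 2.40e-05, estimated-correlation p = 0.684). In C 5 rose and the list did not pass (3 over the list alone, camera adjusted p = 0.132, estimated-correlation p = 0.859), but it passed with quantile normalization (adjusted p = 0.0169), and without the doubtful arrays 8 rose. In alpha 7 fell and none rose at 12 h (7 over the list alone, camera adjusted p = 0.0149, estimated-correlation p = 0.788). MT1E rose by 2.03 ± 0.33 in A (adjusted p = 2.98e-06), MT1M by 2.14 ± 0.45 in D (adjusted p = 0.000443), and MT1G fell by 1.15 ± 0.34 in alpha at 6 h (adjusted p = 0.0126). The members are close paralogs and their probes may read each other's transcripts, so the identity of each is uncertain.

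Genes of cholesterol synthesis and uptake fell in all lines. Of 23 measured, 16 fell and 1 rose in alpha at 24 h (16 and 1 over the list alone, camera adjusted p = 2.34e-05, estimated-correlation p = 0.684). In C 17 fell and 2 rose (18 and 2, camera adjusted p = 4.51e-06, estimated-correlation p = 0.684), and in D 12 fell and 2 rose (13 and 2, camera adjusted p = 0.000336, estimated-correlation p = 0.684). SREBF1, a transcription factor of lipid synthesis, fell by 3.83 ± 0.34 in alpha (adjusted p = 9.20e-13) and 1.71 ± 0.34 in D (adjusted p = 0.000189), and HMGCS1, an early enzyme of the pathway, by 1.84 ± 0.31 in alpha (adjusted p = 3.73e-06). NSDHL, a late enzyme, rose against its pathway by 3.05 ± 0.17 in alpha (adjusted p = 1.82e-18) and 2.24 ± 0.17 in D (adjusted p = 1.54e-13).

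Apoptosis genes split in direction, at a time when 49.4% of all genes were called in alpha (24 h) and 13.7% in D. Of 33 measured pro-apoptotic genes, 12 rose and 7 fell in alpha at 24 h (12 and 7 over the list alone, camera adjusted p = 0.686, estimated-correlation p = 0.894) and 5 rose and 3 fell in D (5 and 3, camera adjusted p = 0.329, estimated-correlation p = 0.788). Without the doubtful arrays 8 rose and 3 fell in D. In alpha, with a single array left, fewer rises were called and the median change was 0.21. The granzyme gene GZMA rose by 4.94 ± 0.50 in alpha at 6 h (at least 7.83-fold) and the death receptor TNFRSF10B by 2.16 ± 0.22 at 24 h, while CASP1, the inflammatory caspase, fell by 2.83 ± 0.44 in alpha and 2.35 ± 0.44 in D. Of 14 measured anti-apoptotic genes, 5 fell and 1 rose in alpha at 6 h (5 and 1, camera adjusted p = 0.0280, estimated-correlation p = 0.684). Among them were BCL2L1 (-2.21 ± 0.32, adjusted p = 5.16e-07) and MCL1 (-1.19 ± 0.31, adjusted p = 0.00345). In D at 6 h all 14 were unchanged by the test (camera adjusted p = 0.568, estimated-correlation p = 0.859). The p53 target list was mixed, with 11 higher and 6 lower of 21 in alpha at 24 h (11 and 6 over the list alone, camera adjusted p = 0.468, estimated-correlation p = 0.894). Without the doubtful arrays, with a single alpha array left, fewer members were called and the median change of the p53 list was 0.79. Its member PLK2, a polo-like kinase, rose in alpha (1.73 ± 0.25, adjusted p = 1.37e-07) and C (2.82 ± 0.25, adjusted p = 8.03e-13) and fell in D (-1.30 ± 0.25, adjusted p = 0.000108).

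Bone and matrix genes also moved in opposing directions. Of all genes, 49.4% were called in alpha at 24 h, 23.7% in B and 13.7% in D. Of 19 measured osteoblast and bone genes, 9 rose and 3 fell in alpha at 24 h (9 and 3 over the list alone, camera adjusted p = 0.577, estimated-correlation p = 0.894). Without the 5 doubtful arrays, which leaves a single alpha array, fewer rises were called and the median change was 0.34. In B 4 rose and 8 fell (4 and 8, camera adjusted p = 0.132, estimated-correlation p = 0.788, and 0.0435 with quantile normalization). MSX2, a homeobox gene of bone formation, rose in alpha by 2.58 ± 0.23 and in D by 2.77 ± 0.23, PTH1R, the parathyroid hormone receptor, rose in D by 3.93 ± 0.50 (at least 3.19-fold), and the collagen gene COL1A1 fell by 2.30 ± 0.26 in C. TNFRSF11B, the decoy receptor that limits bone resorption, fell by 2.31 ± 0.31 in D at 24 h. Of 42 measured matrix and adhesion genes, 15 fell and 5 rose in D at 24 h (16 and 5 over the list alone, camera adjusted p = 0.00239, estimated-correlation p = 0.684). These included the integrin ITGB3 (-3.00 ± 0.85, at least 2.73-fold, adjusted p = 0.0113) and the tenascin gene TNC (-2.83 ± 0.53). In alpha 14 rose and 9 fell (14 and 9 over the list alone, camera adjusted p = 0.895, estimated-correlation p = 0.956). Without the doubtful arrays, which leaves a single alpha array, fewer members were called and the median change was 0.05. THBS2, an anti-angiogenic matrix protein, rose by 4.34 ± 0.52 in C at 6 h (adjusted p = 8.44e-09).

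Clock, stress and interferon genes gave smaller patterns. Of 16 measured clock genes, 6 fell and 1 rose in alpha at 6 h (7 and 2 over the list alone, camera adjusted p = 0.0337, estimated-correlation p = 0.741), a call lost with the replicate number as a block (adjusted p = 0.0502) and with quantile normalization (adjusted p = 0.0912). The clock repressor BHLHE40 fell by 2.87 ± 0.32 in alpha and 1.51 ± 0.32 in D at 6 h, BMAL1 rose by 2.30 ± 0.23 in alpha at 24 h, and PER1, a direct glucocorticoid target elsewhere, rose by 1.98 ± 0.37. Among 20 measured genes of the unfolded protein and integrated stress responses, 12 rose and 2 fell in A at 24 h (12 and 2, camera adjusted p = 0.00545, estimated-correlation p = 0.684). The chaperone DNAJB9 rose by 2.62 ± 0.24 in A and the stress factor ATF3 by 2.20 ± 0.24, whereas TRIB3 fell by 1.85 ± 0.26 at 6 h. Of 24 measured interferon-stimulated genes, 10 fell and 1 rose in A at 24 h (10 and 2, camera adjusted p = 0.215, estimated-correlation p = 0.854), with IFIT1 lower by 2.80 ± 0.35 (at least 4.14-fold, adjusted p = 1.62e-08). Of 25 measured receptor, chaperone and cofactor genes, 10 fell and 2 rose in alpha at 24 h (10 and 2, camera adjusted p = 0.0375, estimated-correlation p = 0.760), a call lost with quantile normalization (adjusted p = 0.103), with the heat-shock gene HSPA1A lower by 3.02 ± 0.22 (adjusted p = 2.23e-15).

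Markers of other cell types were measured as well. KRT5, a basal epithelial keratin, rose in D by 6.92 ± 0.55 at 6 h (at least 25.7-fold, adjusted p = 3.71e-13) and in B by 6.34 ± 0.55 (at least 26.2-fold, adjusted p = 2.17e-12). Of 13 measured epithelial markers, 6 rose and 1 fell in alpha at 24 h (7 and 1 over the list alone, camera adjusted p = 0.418, estimated-correlation p = 0.890). Without the 5 doubtful arrays, which leaves a single alpha array, the higher calls were lost and the median change was 0.47. Of 13 measured haematopoietic markers, 8 rose and none fell in C at 24 h (8, camera adjusted p = 0.0259, estimated-correlation p = 0.773) and 7 rose and 1 fell in alpha (7 and 1, camera adjusted p = 0.0692, estimated-correlation p = 0.796). The C call was lost with quantile normalization (adjusted p = 0.0696). Without the doubtful arrays 6 rose and 1 fell in C. In alpha, with a single array left, fewer rises were called and the median change was 0.99. ITGB2, the leukocyte integrin chain, rose by 5.33 ± 0.29 in alpha at 24 h (adjusted p = 2.43e-19), and the globin gene HBA1 by 5.05 ± 0.43 (adjusted p = 3.28e-13). Across the 17 lists and 15 responses, 77 of 255 camera tests passed, 24 upward and 53 downward, and none passed with the estimated correlation.

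How alike the responses were was asked by overlap. At 6 h, 1658 genes rose in both alpha and A against 247 expected by chance, 1137 fell in both and 2 moved oppositely (correlation of all changes 0.853). Alpha and D shared 705 rises against 124 expected and 414 falls, with 20 in opposite directions (correlation 0.563). By 24 h, B and D shared 1189 rises against 174 expected (correlation 0.801), and alpha and D had 90 genes in opposite directions, PLK2 among the listed genes that did so. Changes in different lines share no untreated arrays, but untreated arrays of 1 replicate number shared a slide set, which the expected numbers leave out. Of the genes called in alpha at 24 h, the median change, signed by the direction in alpha, was 0.99 in A, 1.18 in C, 0.58 in B and 0.41 in D. RGS2 shows the ordering, with rises of 5.77 ± 0.25 in alpha, 6.92 ± 0.25 in A, 6.96 ± 0.25 in C, 4.52 ± 0.25 in B and 3.65 ± 0.25 in D.

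Whether the mean response differed between lines was tested for all 10 pairs and by a joint F test, in which 3024 of 21361 genes (14.2%) had a line-dependent response. D against alpha gave 1119 genes with a higher and 1506 with a lower response, and in 85.6% of the 2625 the change was smaller in D. The mean response of the globin gene HBM was 8.79 in alpha and 1.78 in D, a difference of -7.01 ± 0.69 (129-fold, adjusted p = 3.02e-10), and that of HBZ, another globin gene, was 7.79 in alpha and 1.21 in D (-6.58 ± 0.58, 96.0-fold, adjusted p = 2.49e-11). CADPS, a gene of vesicle release, had a mean response of 6.71 in alpha, while no D group had it above background on all arrays. Its difference was called (adjusted p = 2.56e-08), but where a line has no group above background on all arrays the size is not given here or below. In the other direction, CILP, a cartilage matrix protein, had a mean response of 7.69 in D and 3.07 in alpha (4.62 ± 0.46, adjusted p = 4.71e-10), and the collagen COL15A1 one of 3.47 in D and -1.58 in alpha (5.05 ± 0.46, adjusted p = 6.54e-11). RGS2 responded less in D (-1.63 ± 0.29, adjusted p = 5.54e-05) and so did NOS2 (-2.81 ± 0.26, adjusted p = 1.02e-10). Of the 40 S-phase and mitosis genes, 7 responded higher in D, that is fell less (11 over the list alone, camera adjusted p = 1.12e-05, estimated-correlation p = 0.609, and 14 without the doubtful arrays), among them RRM2 (1.40 ± 0.38, adjusted p = 0.00845) and CCNA2 (1.18 ± 0.32, adjusted p = 0.00914). Of 42 matrix genes, 7 responded lower in D (9, camera adjusted p = 7.85e-05, estimated-correlation p = 0.322), including TIMP3, an inhibitor of matrix proteases (-2.50 ± 0.36, adjusted p = 1.54e-06). The number called ran from 1077 (median scaling) to 4986 (arrayWeights) over the alternatives.

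D was compared with C, A and B as well. Against C, 854 genes had a higher and 1395 a lower response, the change being smaller in D for 91.3% of 2249. HBM differed by -7.91 ± 0.69 (adjusted p = 1.99e-11), HBZ by -6.96 ± 0.58 (adjusted p = 7.33e-12), and CADPS was also lower in D (adjusted p = 1.28e-10). PDYN, an opioid peptide precursor, was higher in D (adjusted p = 0.00173), as were MYZAP, a cardiac junction protein, by 2.95 ± 0.72 (adjusted p = 0.00449) and KRT5 by 2.42 ± 0.64 (adjusted p = 0.00839). In the S-phase and mitosis list 16 members responded higher in D than in C (22 over the list alone, camera adjusted p = 5.32e-12, estimated-correlation p = 0.541), including TTK (1.35 ± 0.29, adjusted p = 0.00122). Against A, 506 genes were higher and 1089 lower, with CADPS lower (adjusted p = 3.90e-11), HBM at -7.25 ± 0.69 (adjusted p = 2.27e-10) and HBZ at -7.21 ± 0.58 (adjusted p = 2.96e-12), and GASK1A, a Golgi kinase-like protein, at 4.04 ± 0.46 (adjusted p = 2.06e-08). Median scaling gave 114 and 517 for D against A. Against B, 24 were higher and 214 lower. The lower ones included CADPS (adjusted p = 8.31e-06), the adhesion gene NTM at -4.61 ± 0.52 (adjusted p = 1.40e-07) and CHRDL2, a BMP antagonist (adjusted p = 1.40e-07), and the higher ones ARHGAP22 at 2.88 ± 0.62 (adjusted p = 0.00536) and PTHLH, a hormone of bone turnover, at 2.31 ± 0.57 (adjusted p = 0.0259). Over the alternatives the numbers called ran from 792 to 3675 against C, 631 to 3148 against A and 110 to 707 against B, and with the slide set as a block they were 3675, 3148 and 604. The probes of GASK1A went the same way, or changed by less than 1.5-fold in 1 of them, in 12 of 15 comparisons only. With normexp the calls of PDYN and KRT5 against C, and of CADPS, NTM and CHRDL2 against B, were lost.

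B against alpha gave 711 genes with a higher and 788 with a lower response, and 74.6% of the 1499 changed less in B. The mean response of NTM was 2.20 in B and -2.40 in alpha, a difference of 4.60 ± 0.52 (24.3-fold, adjusted p = 5.05e-08), and the chemerin receptor CMKLR2 was likewise apart (4.36 ± 0.49, adjusted p = 3.95e-08). RTL3, a retrotransposon-derived gene, responded higher in B (4.48 ± 0.80, adjusted p = 0.000168). FRG2, a gene with near-identical copies and so of uncertain identity, had a mean response of 4.79 in alpha and 0.04 in B (-4.75 ± 0.55, adjusted p = 5.83e-08). The phosphatase PTP4A3 had one of 3.06 in alpha and -1.41 in B (-4.47 ± 0.46, adjusted p = 5.36e-09), and the protease MMP10 one of 5.51 in alpha and 1.06 in B (-4.45 ± 0.61, adjusted p = 1.57e-06). TIMP3 responded lower in B (-3.35 ± 0.36, adjusted p = 1.19e-08). Of 14 anti-apoptotic genes, 4 responded higher in B (5 over the list alone, camera adjusted p = 0.00439, estimated-correlation p = 0.174), among them CFLAR, an inhibitor of caspase 8 (1.53 ± 0.35, adjusted p = 0.00299), and the co-chaperone BAG3 (1.40 ± 0.27, adjusted p = 0.00039). Of 22 inflammatory genes, 5 responded lower in B (8, camera adjusted p = 0.0340, estimated-correlation p = 0.639), including IL1B (-2.80 ± 0.70, adjusted p = 0.00785), and with quantile normalization the call was lost (adjusted p = 0.129). The number called ran from 579 (median scaling) to 4544 (arrayWeights), with 2750 when the slide set was a block.

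A and C were compared with alpha in the same way. A against alpha gave 79 higher and 60 lower. Higher in A were the guidance gene SEMA3D (3.43 ± 0.64, adjusted p = 0.00258), CMKLR2 (3.26 ± 0.49, adjusted p = 0.000104) and HLA-DPB1, an antigen-presenting chain (2.96 ± 0.49, adjusted p = 0.000585), and lower were MMP10 (-3.87 ± 0.61, 14.6-fold, adjusted p = 0.000208), the ephrin receptor EPHA4 (-3.10 ± 0.45, adjusted p = 6.03e-05) and ITGB2 (-2.94 ± 0.33, adjusted p = 3.37e-07). C against alpha gave 291 higher and 186 lower. Among them were RTL3 (4.96 ± 0.80, adjusted p = 8.73e-05), the helicase TDRD9 (3.96 ± 1.04, adjusted p = 0.0268), COL15A1 (3.81 ± 0.46, adjusted p = 4.40e-07), MMP10 (-3.26 ± 0.61, adjusted p = 0.000699), GLT1D1 (-2.89 ± 0.31, adjusted p = 3.11e-08) and the phosphatase PTPN7 (adjusted p = 7.40e-05). The metallothioneins separated alpha from each other line. Of 11 members, 8 responded higher in A (9 over the list alone, camera adjusted p = 9.73e-26, estimated-correlation p = 0.00657), 9 in B (9, camera adjusted p = 3.36e-09, estimated-correlation p = 0.276), 4 in C (9, camera adjusted p = 3.28e-10, estimated-correlation p = 0.267, and 8 without the doubtful arrays) and 9 in D (9, camera adjusted p = 3.36e-09, estimated-correlation p = 0.276). MT1G responded higher by 2.11 ± 0.40 in A (adjusted p = 0.00287) and 2.16 ± 0.40 in D (adjusted p = 0.000114), and MT1M by 2.23 ± 0.52 in C (adjusted p = 0.00914). IGFBP1, a glucocorticoid-induced binding protein of insulin-like growth factors, responded higher than in alpha in A (2.78 ± 0.48, adjusted p = 0.000994), B (2.76 ± 0.48, adjusted p = 0.000109) and C (2.49 ± 0.48, adjusted p = 0.00123). With normexp the calls of SEMA3D, CMKLR2, HLA-DPB1 and MMP10 in A and of MMP10, GLT1D1 and PTPN7 in C were lost, and TDRD9 was lost with arrayWeights. The numbers called ran from 50 to 916 for A and 150 to 1256 for C, both lowest with median scaling, were 65 and 279 at the fewest with 1 array left out, and were 399 and 1256 with the slide set as a block.

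Among the remaining pairs, B against A gave 76 higher and 217 lower. GASK1A (3.44 ± 0.46, adjusted p = 4.07e-06) and TMEM266 (2.61 ± 0.57, adjusted p = 0.00656) responded higher in B and FRG2 (-5.81 ± 0.55, adjusted p = 3.08e-09), the bile transporter SLC51B (adjusted p = 0.0256) and the potassium channel KCNK10 (adjusted p = 0.00142) lower. C against A gave 53 higher and 11 lower. GASK1A (4.30 ± 0.46, adjusted p = 7.32e-08), the chemokine CCL4 (3.91 ± 0.75, adjusted p = 0.00489) and CTCFL, a germline relative of CTCF (3.42 ± 0.60, adjusted p = 0.00142), responded higher in C and CDCA7, a MYC target (adjusted p = 4.66e-08), lower, which reflects a fall in C alone because CDCA7 was not above background on any A array. C against B gave 423 higher and 191 lower. HBM (4.36 ± 0.69, adjusted p = 7.27e-05), CXCL1 (adjusted p = 0.00250) and FRG2 (4.10 ± 0.55, adjusted p = 8.15e-06) responded higher in C and NTM (-3.33 ± 0.52, adjusted p = 7.10e-05) lower. With normexp the calls of GASK1A in both comparisons, SLC51B, KCNK10, CTCFL, CXCL1 and NTM were lost, and TMEM266 was lost under 4 settings. The split of C against B was 214 and 47 with normexp and 121 and 26 with median scaling. Over the alternatives the numbers ran from 105 to 1752 for B against A, 14 to 245 for C against A and 147 to 1531 for C against B, and with the slide set as a block they were 809, 223 and 1391. In all, 59 of 170 camera tests of differences passed, and 1 with the estimated correlation, that of the metallothioneins in A against alpha.

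What set the lines apart before treatment was asked of the untreated arrays, each line against alpha. A had 846 genes higher and 874 lower, B 1080 and 1186, C 1060 and 951, and D 1109 and 850. Some genes were far lower in a single line. CDCA7 was lower in A by 8.43 ± 0.23 (at least 106-fold, adjusted p = 6.72e-30), as were the engulfment adaptor GULP1 (-5.93 ± 0.40, at least 17.9-fold, adjusted p = 1.04e-14) and ANXA10 (-8.33 ± 0.59, 322-fold, adjusted p = 3.30e-14). Lower in B were FBXO25, a ubiquitin ligase subunit (-8.05 ± 0.27, at least 76.0-fold, adjusted p = 5.66e-26), and ERICH1 (-5.85 ± 0.20, at least 12.0-fold, adjusted p = 1.61e-25). Higher in A were the small heat-shock gene HSPB2 (5.26 ± 0.42, adjusted p = 1.25e-12) and the meiotic kinase AURKC (5.15 ± 0.39, at least 16.6-fold, adjusted p = 2.99e-13). MLPH, a melanosome transport gene, was higher in B (5.89 ± 0.40, adjusted p = 8.61e-15), C (5.31 ± 0.40, adjusted p = 3.84e-13) and D (5.53 ± 0.40, adjusted p = 6.95e-14), although its probes disagreed. The trefoil peptide TFF2 was higher in B (5.70 ± 0.47, adjusted p = 3.75e-12). BST2, which tethers virus particles, was lower in A (-1.81 ± 0.47, adjusted p = 0.00892), B (-5.52 ± 0.47, adjusted p = 7.97e-12), C (-4.26 ± 0.47, adjusted p = 1.01e-08) and D (-4.51 ± 0.47, adjusted p = 2.94e-09). HHIP, a hedgehog antagonist, was higher in C (5.29 ± 0.87, at least 12.2-fold, adjusted p = 2.78e-05) and D (4.99 ± 0.87, at least 9.96-fold, adjusted p = 6.75e-05), and the galectin LGALS9 was lower in C (-4.84 ± 0.35, adjusted p = 1.04e-13). Within single slide sets 99.1 to 100% of these genes had the same direction, which is no separate test because the same arrays called them. With the slide set as a block 2653 genes differed in A, 3131 in C and 3152 in D, but a fit of only the groups compared gave 604 in A, 705 in B, 295 in C and 351 in D, and median scaling 642, 857, 800 and 831. With 1 array left out D fell to 1263 at the fewest.

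The gene groups also differed before treatment. Of 22 inflammatory genes, 9 were higher and none lower in A than in alpha (9 over the list alone, camera adjusted p = 0.000240, estimated-correlation p = 0.399). There were 9 higher in C (11, camera adjusted p = 2.30e-07, estimated-correlation p = 0.160) and 5 in D (6, camera adjusted p = 0.00131, estimated-correlation p = 0.444). CCL2 was higher by 3.83 ± 0.59 in A (adjusted p = 1.01e-05) and 4.05 ± 0.59 in D (adjusted p = 3.46e-06). Of 42 matrix genes, 17 were higher and 2 lower in D (19 and 3, camera adjusted p = 1.06e-08, estimated-correlation p = 0.0598), with the laminin gene LAMA4 at 4.79 ± 0.93 (at least 6.74-fold, adjusted p = 0.000316) and the cadherin CDH11 at 2.71 ± 0.38 (adjusted p = 1.57e-06). Of 11 metallothioneins, 9 were lower in A (9, camera adjusted p = 4.50e-10, estimated-correlation p = 0.139), for instance MT1E (-1.95 ± 0.33, adjusted p = 5.60e-05). Of 23 cholesterol genes, 11 were lower in B (12, camera adjusted p = 1.06e-08, estimated-correlation p = 0.160), such as HMGCS1 (-1.79 ± 0.31, adjusted p = 5.96e-05) and SQLE (-1.26 ± 0.25, adjusted p = 0.000345). Of 19 bone genes, 4 were higher in C (5, camera adjusted p = 0.00135, estimated-correlation p = 0.259), with BMP6 at 3.11 ± 0.39 (adjusted p = 1.66e-07), and TNFRSF11B was higher in every line against alpha, by 2.08 ± 0.31 in A to 3.22 ± 0.31 in D. In total 24 of 68 camera tests passed and none with the estimated correlation.

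The last question was which changes came late, comparing 24 h with 6 h. In alpha 4186 genes were higher and 3931 lower, in A 2031 and 3168, in B 1337 and 2436, in C 2955 and 3222, and in D 704 and 943. The D result was fragile: 9 genes were called in a fit of only the groups compared and 578 with D 24 h replicate 3 left out. The same fit gave fewer in alpha (2770) and C (2991) but more in B (5790, against 3773 in the main fit). TRIM63, a muscle atrophy ubiquitin ligase, rose late in alpha by 5.81 ± 0.73 (at least 52.2-fold, adjusted p = 3.25e-08), and NEFH, a neurofilament chain, rose in alpha (5.65 ± 0.66, adjusted p = 6.21e-09) and C (5.52 ± 0.66, at least 14.8-fold, adjusted p = 2.17e-08). FOXJ1, a factor of motile cilia, rose late in A (5.34 ± 0.91, at least 20.9-fold, adjusted p = 1.89e-05) and C (5.26 ± 0.91, at least 20.4-fold, adjusted p = 1.59e-05). The protocadherin PCDH8 rose late in A (5.34 ± 0.30, adjusted p = 3.93e-17), and the immediate-early gene FOSB in C (5.05 ± 0.58, adjusted p = 1.11e-08). IL1RL1, the interleukin-33 receptor, rose late in A (5.09 ± 1.10, adjusted p = 0.000495) and B (4.13 ± 1.10, at least 6.49-fold, adjusted p = 0.00611), and ESM1, an endothelial secreted proteoglycan, in D (3.86 ± 0.59, adjusted p = 3.71e-05). ANXA3 fell late in alpha (-4.76 ± 0.33, adjusted p = 1.96e-14). So did CHST15, which sulfates chondroitin, in A (-4.11 ± 0.49, at least 5.49-fold, adjusted p = 3.06e-08) and C (-3.89 ± 0.49, adjusted p = 5.73e-08), MYT1 in B (-4.48 ± 0.57, adjusted p = 4.34e-07) and KRT75 in D (-5.88 ± 0.79, at least 24.9-fold, adjusted p = 5.30e-06). Scaling moved these splits: quantile normalization gave 2200 and 2267 in A, 1285 and 1474 in B, and 1122 and 712 in D. Median scaling gave 1667 and 5155 in alpha, 1341 and 1020 in A, 897 and 4424 in C, and 547 and 194 in D, and in B it called 1167 genes in both directions together. The values processed by the authors gave 3047 and 4762 in alpha, 2199 and 2215 in A, 1229 and 1434 in B, and 1141 and 583 in D. Normexp gave 6651 and 3246 in alpha.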

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

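The tests below of the D line, metallothioneins and haematopoietic markers address patterns already seen, so none is taken as set before the data were examined. What drew attention in each result here is the same: a group of samples, the line, differed from another in its response, by a test of the difference itself. The F test over the line-by-time terms called 3024 genes. Between pairs of lines the mean response differed for 139 genes in A against alpha, 1499 in B against alpha, 477 in C against alpha and 2625 in D against alpha. It differed for 293 genes in B against A, 64 in C against A and 1595 in D against A, for 614 in C against B and 238 in D against B, and for 2249 in D against C.

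Each comparison was set beside other splits of its own arrays, on the 21361 genes measured on all arrays. For 3 against 3 arrays only 10 splits exist, so the real one can at best be 1 of 10, and it was in all 24 such comparisons. For 6, 12 and 24 h the genes called in the real split and in the highest other were 3854 and 1371, 6269 and 457, and 10586 and 1222 in alpha, and 3987 and 1, 7062 and 0, and 8080 and 0 in A. They were 2466 and 0, 4733 and 0, and 5089 and 0 in B, 4764 and 2, 9265 and 1385, and 9912 and 584 in C, and 1904 and 565, 2178 and 1, and 2948 and 76 in D. Untreated against alpha they were 1703 and 227 for A, 2230 and 126 for B, 1980 and 211 for C, and 1947 and 1611 for D. For 24 h against 6 h they were 7970 and 290 in alpha, 5098 and 0 in A, 3715 and 0 in B, 6058 and 93 in C, and 1621 and 5 in D.

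Between pairs, 100 splits were made. As many genes as in the real split were called in 1 for D against alpha (2585, highest other 1626), B against A (291 and 281), D against A (1579 and 818), C against B (604 and 251) and the F test (3024 and 4), the real split included. The number was 3 for B against alpha (1465 and 2573), C against A (66 and 165) and D against C (2217 and 4794). For A against alpha it was 10 (130 and 1582), for C against alpha 10 (463 and 2172) and for D against B 5 (237 and 1055). The splits did not hold the slide set fixed, and with it as a block these last 3 pairs gave 399, 1256 and 604 genes. Line labels were shuffled separately within each time. A split could therefore turn differences between untreated lines into a difference in response, so these splits are no fair null for the pairs or the F test. A difference from the grouping of arrays alone was neither shown nor excluded for any pair. Besides such line differences, slide sets and the doubtful arrays may add to the high counts of other splits, and their cause was not tested.

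The changes were smaller in D than in the other lines. Over genes called in A, the median change in D was 0.548, 0.466 and 0.403 of that in C at 6, 12 and 24 h. The line nearest to D was B, with medians of 0.88, 0.88 and 0.80 over these genes against 0.65, 0.58 and 0.50 in D. The checks of scaling and arrays were made against C only. At 12 and 24 h the ratio to C was at most 0.438 under the 4 other scalings, and without the doubtful arrays at most 0.473 at any time. This excludes both as the whole cause of the difference from C at 12 and 24 h. At 6 h normexp gave 0.846, so the size of the 6 h difference may depend on the background correction. Untreated D minus alpha in the direction of the response had a median of 0.0222 (quartiles -0.344 to 0.380). Untreated C was not compared, so D starting part of the way stayed open. A weaker response to form D, or of this clone, stayed open at 12 and 24 h, not separable by the design.

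The metallothioneins fell in alpha at 6 and 12 h and rose in A, B and D by 24 h, none of which passed with the correlation estimated; in C the list passed with quantile normalization only. The fall at 12 h was no product of a single untreated alpha array or of the scaling: its median was at its weakest -0.965 with each such array left out, and -1.06 over 4 scalings. Members did not all read 1 transcript, as the lowest correlation between them was -0.293. The median was 0.847 and the highest 0.995, so cross-reading among the closest members could not be excluded. Untreated alpha cells had the highest mean level of the list (5.12, against 3.58 to 4.35), so a line that starts high, by receptor form or clone, remains open.

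Some haematopoietic markers rose late in alpha and C, although the list did not pass in alpha (camera adjusted p = 0.0692) and was lost in C with quantile normalization (0.0696) or the estimated correlation (0.773). Without the doubtful arrays, which leaves a single array of alpha at 24 h, the calls numbered 13 against 22. This leaves open how much those arrays added. A rise of all dim probes was left open too: its test over tested genes dim in untreated C (median 2.49 at 24 h) decides nothing, since the filter keeps such genes for being brighter elsewhere, and over all genes dim in the other untreated lines, filtered or not, the median was 1.47, and 0.366 without the doubtful arrays. Only 1 of the 8 members called in C was dim there before treatment and 2 were above background on all 3 untreated arrays. Whether the receptor form drives a real rise was not settled.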

How the results depend on the processing

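Leaving out the doubtful arrays was added after the array signals had been seen, and it leaves a single array of alpha at 24 h. Signal over background limits what was testable: 45.5 to 85.9% of spots were well above background, so changes in dim genes rest on surrogate values, and the difference between a gene absent and a gene dim is not resolved. A result is taken as moved when the number of genes called left the range of 2/3 to 3/2 of its main value, and every moved value is given.

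All numbers of called genes stayed within range under quantile normalization (0.731 to 1.11 of the main value), the mean of a gene's probes (0.892 to 1.08), the values processed by the authors (0.683 to 1.08) and the slide set as a random block (0.930 to 1.02). Of 384 counts with 1 array left out, 364 stayed. Of 5736 comparisons for 100 named genes, 5601 kept direction and side of the threshold, 88 lost and 47 gained the call, and none reversed. For the moves below the cause was not tested, except that a filter on all 60 arrays tests fewer genes and a fit of only the groups compared uses fewer arrays.

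With normexp the responses at 6 h became 2566 in alpha (main 3915), 2481 in A (4049), 1574 in B (2505), 2841 in C (4842) and 3321 in D (1939), and D at 12 h became 1394 (2219). Differences between lines became 52 for A against alpha (139), 845 for B (1499), 211 for C (477) and 1385 for D (2625), 171 for B against A (293), 14 for C against A (64), 839 for D against A (1595), 261 for C against B (614), 110 for D against B (238) and 1014 for D against C (2249). Untreated lines became 962 for A (1720), 1298 for B (2266), 1180 for C (2011) and 1128 for D (1959), and 24 h against 6 h became 3431 in A (5199), 2358 in B (3773) and 3993 in C (6177).

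Median scaling gave 2518 in alpha at 6 h, 3078 and 3186 in B at 12 and 24 h (4821 and 5179), and 1313 and 1666 in D (2219 and 3000). Between lines it gave 50 for A, 579 for B, 150 for C and 1077 for D against alpha, 105 for B, 24 for C and 631 for D against A, 147 for C and 153 for D against B, and 792 for D against C. Untreated lines gave 642 in A, 857 in B, 800 in C and 831 in D, and 24 h against 6 h gave 2361 in A, 1167 in B and 741 in D (1647).

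Without a filter on dim probes only C against A moved, to 42. With the filter on all 60 arrays, 6, 12 and 24 h became 2440, 4129 and 6566 in alpha (3915, 6369 and 10789), 2443, 4574 and 5455 in A (4049, 7181 and 8231), and 3113, 5873 and 6255 in C (4842, 9458 and 10103). B at 6 h became 1453, and D at 6 and 12 h 1096 and 1431. Differences became 84 for A against alpha, 187 for B and 26 for C against A, and 154 for D against B, and the genes higher in all 5 lines became 275 at 6 h (592) and 464 at 12 h.

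In a fit of only the groups compared, alpha at 24 h gave 6427, C at 12 and 24 h 4624 and 6097, and D 262, 1077 and 1972 at 6, 12 and 24 h. C against alpha gave 160, D against alpha 1584, B against A 867 and D against C 1169. Untreated lines gave 604 in A, 705 in B, 295 in C and 351 in D, and 24 h against 6 h gave 2770 in alpha (8117), 5790 in B, 2991 in C and 9 in D.

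Replicate number as a block gave 282 for A, 2356 for B and 965 for C against alpha, 596 for B, 185 for C and 2693 for D against A, 1343 for C and 439 for D against B, 3442 for D against C, and 2989 for 24 h against 6 h in D. Line-by-replicate gave, in the same order, 337, 2440, 1087, 690, 245, 2760, 1454, 466, 3533 and 3022. The scanner as a block moved only 24 h against 6 h in D, to 2899. The slide set as a block gave 399 for A, 2750 for B, 1256 for C and 4188 for D against alpha, 809 for B, 223 for C and 3148 for D against A, 1391 for C and 604 for D against B, 3675 for D against C, and 2653, 3131 and 3152 for untreated A, C and D.

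Replicate numbers were not treated as pairs, because the labels do not say that they mark 1 culture and not every pair correlated above 0.1. Residuals of 1 line with the same number at different times correlated above 0.1 in 68 of 90 pairs (lowest -0.23, median 0.22, highest 0.76) and with different numbers in 21 of 180. Residuals of different lines with the same time and number, which shared a slide set, did so in 98 of 120 pairs (median 0.31). Arrays of different times lay on different slide sets, so shared slides do not account for the correlation across times. It is a hint from the data and not from the design, and its cause was not tested.

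With arrayWeights alpha at 6 h gave 6806, B at 6 and 12 h 4161 and 7566, and D at 12 h 3694. Differences were 916 for A, 4544 for B, 1241 for C and 4986 for D against alpha, 1752 for B, 163 for C and 2682 for D against A, and 1531 for C and 707 for D against B. Untreated lines gave 3917 in A, 4697 in B, 3280 in C and 3828 in D, and 24 h against 6 h gave 6772 in B. Without the doubtful arrays C against alpha gave 776, B against A 545, C against A 109, D against A 2586, D against B 378, and 24 h against 6 h in alpha 5000.

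Leaving out each array in turn gave 65 to 184 genes for A against alpha (moved at 65, 67 and 91), 279 to 565 for C against alpha (moved at 279), and 1263 to 2223 for untreated D (moved at 1263 and 1299). C against A ranged from 31 to 76 (moved at 31, 31, 35 and 42), C against B from 369 to 698 (moved at 369, 383 and 408), D against A from 968 to 1860 (moved at 968) and D against B from 151 to 303 (moved at 151). D at 6 h ranged from 1167 (replicate 3 left out) to 3258 (replicate 1 left out), and 24 h against 6 h in D from 578 to 2514 (moved at 578, 1042 and 2514).

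Of the gene-list tests, 77 responses, 59 differences and 24 untreated differences passed at the preset correlation, and 0, 1 and 0 with the correlation estimated from the data. The median change of a list turned in 4 cases: inflammatory genes in D at 6 h with normexp (0.14, main -0.19), matrix genes in A against alpha with median scaling (0.02, main -0.05), and with arrayWeights classical glucocorticoid-induced genes in A against alpha (-0.05, main 0.67) and S-phase and mitosis genes in C against alpha (0.04, main -0.20).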

Other observations

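The tests of neighbouring genes and of genes missing from a line were chosen after the untreated differences had been seen. Untreated lines also differed in genes that no paragraph above describes, each against alpha with limma. CDKN1A, which encodes the cell cycle inhibitor p21, was higher in A (0.91 ± 0.15, adjusted p = 4.30e-05), B (1.29 ± 0.15, adjusted p = 3.97e-08), C (0.95 ± 0.15, adjusted p = 1.74e-05) and D (1.13 ± 0.15, adjusted p = 8.34e-07). The clock gene NPAS2 was higher in B (2.09 ± 0.28, adjusted p = 7.58e-07) and D (1.96 ± 0.28, adjusted p = 3.01e-06). Of the pro-apoptotic genes, BIK was lower in D (-2.61 ± 0.33, adjusted p = 2.66e-07) and PMAIP1 higher (1.41 ± 0.20, adjusted p = 1.40e-06). The epithelial markers KRT14 (3.67 ± 0.43 in A, adjusted p = 3.89e-08) and EPCAM (3.23 ± 0.41 in B, adjusted p = 1.75e-07) were higher. Of 24 interferon-stimulated genes, 2 were higher and 8 lower in B (2 and 9 over the list alone, camera adjusted p = 0.0128, estimated-correlation p = 0.470), with IFI27 lower (-2.56 ± 0.25, adjusted p = 5.14e-10) and MX2 higher (2.16 ± 0.51, adjusted p = 0.00306). Of 20 genes of the unfolded protein and integrated stress responses, 3 were higher in C (6 over the list alone, camera adjusted p = 0.00157, estimated-correlation p = 0.444).

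In the first principal component of all arrays (29.8% of the variance; the next had 12.8%), untreated groups lay between -96.4 and -80.2. At 24 h the group means were 106 in alpha, 98.8 in C, 59.5 in A and 8.49 in B, and in D the mean stayed below 0.

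Neighbouring genes differed together between lines. The hypothesis, segments differing in copy number between clones, would shift runs of neighbouring genes the same way. Over all times, treated arrays included, 960 of 46095 windows of 11 genes had a median difference over 0.5 from the other lines. At most 33 did in 1000 permutations of gene order (mean 6.82). This fits the hypothesis, but neighbours regulated together or line-dependent responses could give the same and copy number was not measured. Runs included 71 genes from NOC2L to MAD2L2 higher in alpha (69 of them, median 0.78), 37 from USP25 to RCAN1 higher in alpha (all 37, median 0.70), 37 from MYOM1 to ABHD3 lower in A (35, median -0.62) and 29 from MFRP to B3GAT1 lower in B (28, median -0.78). In C 55 genes from TRNT1 to HACL1 were higher (all 55, median 0.62), and in D 40 from NEFL to RAB11FIP1 were lower (36, median -0.72) and 32 from ZBTB14 to ABHD3 higher (all 32, median 0.62).

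Some genes were not above background on any array of 1 line while measured in the others: ST8SIA1, PSTPIP2 and ZNF93 in alpha, CDCA7 and GULP1 in A, and FEZ1, FBXO25, ERICH1 and FAM167A in B. Loss of a segment was tested by counting neighbours among these 9 genes. There were 0 neighbouring pairs (permutation p = 1), and with so few genes the test could not tell. FBXO25, ERICH1 and FAM167A lie on chromosome 8 and CDCA7 and GULP1 on chromosome 2, which was seen afterwards and not tested.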
